A study of Mus musculus with 32 samples.

How the data were processed

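The series held 32 single-nucleus RNA libraries from mouse retina (strain C57BL/6J), and the groups compared were mice lacking the miR-9-2 hairpin in all cells with wildtype at E16.5, P0 and 3 weeks and a knockout of a putative miR-9-2 enhancer with wildtype at 5 weeks. Per the labels, nuclei came from flash-frozen tissue; the 3-week libraries were made with a Multiome kit (chromatin and RNA) and the others with a 3-prime gene expression kit. Per the submitters' processing notes, the authors used Cell Ranger, Seurat and the mm10 build. Versions, the gene annotation, any removal of free RNA and the read lengths were not given in the sources used here. The deposited values were whole-number UMI counts per gene and barcode, and every step after them was run anew. The files listed 32285 genes for E16.5, P0 and 3 weeks and 33696 genes for 5 weeks, with 31950 gene IDs in both, so the 5-week annotation differed from the others. The chromatin part of the Multiome assay and the authors' own cell labels were not among the deposited data used here.

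The 32 files held 383159 barcodes. Barcodes with at least 200 detected genes and at most 5% mitochondrial counts were kept (268970). Doublets were scored with Scrublet as built into Scanpy 1.11.5. The automatic threshold marked under 0.5% of barcodes in 29 of the 32 libraries, so the highest-scoring barcodes were removed at 0.8% per 1000 nuclei with a ceiling of 10%, which left 249551 nuclei. Each stage was clustered alone: counts scaled to 1000 per nucleus, 2000 variable genes, 30 principal components, 20 neighbours and Leiden at resolution 1.0 (Python 3.11.15, AnnData 0.12.19, igraph 0.11.9, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, Matplotlib 3.10.9). No batch correction was applied before clustering.

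Clusters were named by fixed marker genes of 19 classes, and a class is written as class-like because the name rests on those markers alone. A name needed at least 3 markers raised at least 2-fold, a mean marker score above the set limit and a lead of 0.1 over the next class, and clusters with over 20% doublets were not named. The limits for naming were set after the data were seen. Named were 15 of 21 clusters at E16.5, 16 of 21 at P0, 32 of 45 at 3 weeks and 37 of 50 at 5 weeks. Batches are named by the month in their labels (March and December, and February, which labels 1 batch of 3-week libraries and another of E16.5 and P0 libraries). In the E16.5 and P0 libraries of the December batch most nuclei stayed without a class name (means 84.5% and 78.5% in the knockout, 88.9% and 80.1% in wildtype), against 6.71% and 6.31% (knockout) and 11.0% and 7.84% (wildtype) in the February batch. The classes of E16.5 and P0 in the December batch therefore rest on a small part of its barcodes.

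Counts were summed per library and class, and classes with at least 20 nuclei in at least 2 libraries per group were tested (25 fits; 3-week microglia, 5-week horizontal and 5-week microglia were too few). The test was edgeR 4.0.16 quasi-likelihood with TMM scaling and batch as a covariate (R 4.3.3, limma 3.58.1), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its fit. Log2 fold changes are knockout over wildtype with the standard error (SE) after the sign ±, and a ± after a mean is the standard deviation over libraries. CPM values were averaged over libraries without the batch term. The main comparisons were progenitor-like nuclei at E16.5 and P0 and Müller glia-like nuclei at 3 and 5 weeks, fixed before the data were examined. The genes named are the largest rises and falls among the called genes with an average log2 CPM of at least 3 and the same direction in every pair (up to 8 per direction in a main comparison and 3 in another class), the host transcript, and the 4 members of each list with the smallest p in a main comparison, whether or not they passed. Some items are not reported here. The naming of list members in other classes was chosen after their values were seen.

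Lists of genes (25) were tested with camera at its preset correlation of 0.01, again with the correlation estimated from the data, and with fry. A list member was counted over all genes and also with p adjusted over the list alone. Shares of nuclei were compared by exact permutation of the library labels, and beside it by edgeR on nuclei counts. Seed matches of miR-9 were counted in the 3' UTRs of 20676 genes (GENCODE M21, GRCm38), comparing median log2 fold changes of genes with and without each heptamer. A difference between stages was tested as an interaction in 1 joint edgeR fit.

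Alternatives were no covariate, the pair number as a block in place of batch, other size factors, DESeq2 1.42.0, no filter on low counts, at least 500 genes per nucleus, doublets kept, Leiden at 0.5 and each library or pair left out. Added after the data were seen were each batch alone, 3 weeks without replicate pair 5, and clustering without Onecut1 and Onecut2. Per the series design, equal replicate numbers mark litter- and sex-matched pairs. By its sex genes P0 wildtype replicate 4, labelled female, did not match its label, so that pair was not sex-matched by its counts. The correlation of residual values between libraries of the same number was 0.574 to 0.816 at E16.5, 0.542 to 0.845 at P0, 0.0561 (pair 5) to 0.692 at 3 weeks and 0.0697 to 0.155 at 5 weeks. The highest correlation with a library of another number was 0.494 to 0.767, 0.479 to 0.837, 0.158 to 0.681 and −0.0652 to 0.0172 in the same order, so much of it was not particular to the pair, and in 3 of 16 pairs (E16.5 pair 3, 3-week pairs 3 and 5) another number was higher. No library was a copy of another of the same stage and genotype (50 pairs compared, 0 identical). Libraries of different genotype or stage were not compared in this way. Sex labels were compared with Xist and Ddx3y in each library.

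The pipeline was tested on simulated data with the group sizes and depth of each main comparison. Of genes given a 2-fold change, 20.8% were recovered at E16.5, 60.0% at P0, 40.7% at 3 weeks and 50.6% at 5 weeks, and of genes given a 3-fold change 60.0%, 87.9%, 84.6% and 74.6%. False calls were 3.3%, 9.5%, 3.8% and 3.0% of all calls. The simulated libraries held no batch differences, and each gene had the spread typical of its expression level and not its own. These rates may therefore not hold for the real libraries. For the seed test random fold changes, without groups or depth, were drawn for the genes of P0 progenitor-like nuclei. A shift of 0.1 added to genes with the miR-9-5p seed ranked 1 among heptamers of the same base composition. This does not give the smallest shift that the real data could show.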

Results

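The data were 32 libraries: miR-9-2 knockout and wildtype at E16.5 (4 and 4), at P0 (4 and 4) and at 3 weeks (5 and 5), and miR-9-2 enhancer knockout and wildtype at 5 weeks (3 and 3). Total UMI in replicate order were 6677761, 6426694, 6459945 and 7227249 in E16.5 wildtype and 15676723, 9758512, 4113000 and 8076636 in E16.5 knockout. At P0 they were 7821082, 7308190, 28647479 and 30157311 in wildtype and 7345881, 8108536, 20595871 and 35604102 in the knockout. At 3 weeks they were 17704725, 5711080, 23104981, 14163901 and 4560888 in libraries labelled wildtype and 16361876, 3541931, 21656133, 6051806 and 5279327 in libraries labelled knockout. At 5 weeks they were 18182021, 15775060 and 11536873 in wildtype and 13553933, 17445278 and 13372191 in the enhancer knockout. Kept nuclei in wildtype and knockout, with the range of the libraries' median UMI, were 18650 (725 to 961) and 22785 (469 to 1558) at E16.5 and 61716 (501 to 774) and 64537 (505 to 777) at P0. They were 34196 (458 to 2538.5) and 28418 (591 to 1394.5) at 3 weeks and 9590 (2155.5 to 2654) and 9659 (2032 to 2667) at 5 weeks. The labels of replicate 5 at 3 weeks are in doubt, because both of its libraries lay on the side of the other genotype. Its libraries are called the library labelled wildtype and the library labelled knockout, and the 3-week fits are given with and without them.

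The hairpin of miR-9-2 (13:83738814-83738885, plus strand, GRCm38) lies within the noncoding gene C130071C03Rik (13:83721381-83884194, plus strand, GRCm38), whose counts were the nearest reading of the locus. Over all nuclei the host was at 582, 791, 562 and 634 CPM in E16.5 wildtype and 741, 683, 664 and 871 in the knockout. At P0 it was at 567, 508, 760 and 786 CPM in wildtype and 464, 488, 799 and 928 in the knockout. At 3 weeks it was at 240, 232, 223, 174 and 223 CPM in libraries labelled wildtype and 259, 206, 209, 246 and 188 in libraries labelled knockout. At 5 weeks it was at 239, 233 and 249 CPM in wildtype and 189, 184 and 205 in the enhancer knockout. A deletion of the hairpin alone need not lower its host, so these values do not check the knockout labels. In Müller glia-like nuclei of the 5-week enhancer knockout C130071C03Rik fell (log2 fold change −1.12 ± 0.11, edgeR adjusted p = 0.000232, 1056 to 485 CPM, 3 of 3 pairs). It did not pass in 5-week amacrine-like nuclei (−0.60 ± 0.15, adjusted p = 0.184), where the pair block called it (adjusted p = 0.0107). In the knockout the host did not pass in progenitor-like nuclei at E16.5 (0.18 ± 0.11) or P0 (−0.07 ± 0.08), nor in P0 amacrine-like nuclei (−0.77 ± 0.22, adjusted p = 0.0611).

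The E16.5 comparison asked what losing miR-9-2 changed in progenitors while the early-born neurons are made. No gene passed in progenitor-like nuclei (0 of 10123 by edgeR, n = 4 and 4), with 458 genes at an unadjusted p under 0.05, and DESeq2 called 5 higher and 6 lower. Notch1 (−0.57 ± 0.10, 353 to 239 CPM), its target Hes5 (−0.91 ± 0.19) and Hes6 (−0.66 ± 0.21) were lower without passing. So were the proneural gene Neurog2 (−1.06 ± 0.44), the glial factor gene Sox8 (−1.16 ± 0.20), Nfix (−1.20 ± 0.49), Nfib (−0.61 ± 0.22), Cenpf (−0.38 ± 0.11), Top2a (−0.29) and the host of another miR-9 hairpin, Mir9-3hg (−1.22 ± 0.23). Higher without passing were the VEGF receptor gene Flt1 (16.4 to 38.6 CPM), the Wnt modulator gene Sfrp2 (0.90 ± 0.30) and Foxp4 (1.71 ± 0.64).

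As sets at E16.5, camera at its preset correlation placed 5 of 17 tested lists lower. They were G2 and M phase genes (52 measured, adjusted p = 1.12e-08), neurogenic transcription factors (16, adjusted p = 1.12e-08), the Notch pathway (19, adjusted p = 9.04e-06), late-competence progenitor genes (13, adjusted p = 0.00303) and the miR-9 hosts with their neighbours (4, adjusted p = 0.00303). With the correlation estimated from the data these had p = 0.156, 0.0360, 0.00718, 0.0162 and 0.0534 in the same order. None passed after adjustment (lowest adjusted p = 0.122). No member of any of these lists passed over all genes. Adjusted over the list alone, 1 Notch pathway gene rose and 4 fell, 1 late-competence gene and 1 host gene fell, and no G2 and M phase gene or neurogenic transcription factor passed. In the February batch cluster 1, led by Aspm, Kif23 and Cenpe, held 63.3 and 64.6% of progenitor-like nuclei in wildtype and 51.0 and 48.4% in the knockout, and cluster 3, led by Hells and Pcna, 36.6 and 34.6% and 48.9 and 51.4%. Fewer dividing nuclei and lower expression of G2 and M phase genes were therefore not told apart. The December batch had 92.7 to 98.5% in cluster 9. Without the filter on low counts 174 genes were called, and with the December batch alone 15.

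The P0 comparison asked what losing miR-9-2 changed in progenitors when late-born neurons and glia are made. In progenitor-like nuclei 21 genes rose and 55 fell of 12168 tested (edgeR, n = 4 and 4), each named gene in 4 of 4 pairs. Flt1 rose most (2.88 ± 0.33, adjusted p = 0.00976, 10.3 to 78.5 CPM), followed by Atoh7 (2.05 ± 0.35, adjusted p = 0.0449, 4.12 to 17.1 CPM), a factor needed for ganglion cell formation. Tshz2 (2.01 ± 0.25, 49.9 to 197 CPM), Tmem255a (1.92 ± 0.15, adjusted p = 0.00195) and Fstl4 (1.84 ± 0.23, 111 to 353 CPM) rose. Egfem1 (1.59 ± 0.19), Stk33 (1.36 ± 0.16) and the neuregulin gene Nrg3 (1.30 ± 0.17) also rose. The photoreceptor nuclear receptor gene Nr2e3 fell (−2.90 ± 0.46, adjusted p = 0.0341, 16.8 to 2.01 CPM), as it did in amacrine-like (−3.69 ± 0.53) and photoreceptor-like nuclei (−3.08 ± 0.16), so photoreceptor RNA in the droplets was not excluded as its source. Also lower was the guidance receptor gene Robo3 (−2.69 ± 0.29, adjusted p = 0.00811, 26.2 to 3.73 CPM). Foxd2os (38.0 to 8.50 CPM), Nwd1 (−1.93 ± 0.34), the Wnt5a receptor gene Ror2 (−1.88 ± 0.30), Arhgef3 (−1.81 ± 0.22), Rnf220 (−1.64 ± 0.12, adjusted p = 0.00152) and Nav2 (−1.50 ± 0.09, adjusted p = 0.000464, 2110 to 758 CPM) fell. With the pair block Atoh7 (adjusted p = 0.0571), Foxd2os (0.0544), Nwd1 (0.0505) and Ror2 (0.0747) no longer passed.

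Genes of late progenitors fell at P0. Of 15 measured late-competence genes 0 rose and 4 fell (1 rose and 6 fell adjusted over the list alone). The fallen genes were Nfib (−1.19 ± 0.15, adjusted p = 0.0128, 768 to 309 CPM), Nfix (−1.15 ± 0.14, adjusted p = 0.0124), Zfp36l2 (−0.67 ± 0.09) and Rlbp1 (−1.29 ± 0.20, adjusted p = 0.0340). Nfib and Nfix encode nuclear factor I proteins, which late progenitors express. Of 19 Notch pathway genes 0 rose and 3 fell (0 and 5 over the list alone). These were Hes5 (−1.37 ± 0.17, adjusted p = 0.0126, 316 to 114 CPM), Hey2 (−1.27 ± 0.17, adjusted p = 0.0201) and Notch1 (−0.59 ± 0.09, adjusted p = 0.0251, 474 to 322 CPM). Heyl did not pass (−0.61). The sets fell by camera (adjusted p = 2.16e-08 for late-competence genes and 1.58e-08 for the Notch pathway). With estimated correlation both had p = 0.00138 and adjusted p = 0.0145. These were the only 2 of 15 list calls in the 4 main comparisons that held so.

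In P0 progenitor-like nuclei camera also placed lower S phase genes (42 measured, 0 passed over all genes, 0 over the list alone, adjusted p = 0.000289), G2 and M phase genes (52, 0 and 0, adjusted p = 2.95e-05). Also lower were rod genes (4, 1 fell, 3 over the list alone, adjusted p = 0.000179) and mature Müller glia genes (17, 1 fell, 1 rose and 3 fell over the list alone, adjusted p = 0.0343). It placed higher retinal ganglion cell genes (14, 0 passed, adjusted p = 0.000289) and cone genes (8, 0 passed, 3 rose over the list alone, adjusted p = 0.0133). With estimated correlation these 6 had p = 0.0505, 0.176, 0.0560, 0.0663, 0.130 and 0.254 in the same order. Pooled over libraries, cluster 3, with Aspm and Kif23, held 34.7% of wildtype and 28.1% of knockout progenitor-like nuclei. Cluster 2 held 32.4% and 40.1%, cluster 5 held 21.01% and 20.55%, and cluster 10 held 11.9% and 11.2%. Another mix of clusters and lower expression of S phase and G2 and M phase genes were therefore not told apart. Kept nuclei per P0 library ranged from 3823 to 28360 in wildtype and from 4562 to 41919 in the knockout. The pooled shares of progenitor clusters thus also follow the weight of single libraries and batches. The other 13 lists tested at P0 were not called. Of 18 progenitor maintenance genes 2 fell, of 18 neurogenic transcription factors 1 rose (mean 0.08, median −0.13), and of 15 early-competence genes none passed. Of 4 miR-9 hosts and neighbours 1 fell, Mir9-3hg (−1.08 ± 0.15, adjusted p = 0.0220), whose mean over all nuclei went from 86.1 ± 23.0 to 44.3 ± 6.82 CPM. The VEGF receptor gene Kdr fell (−0.80 ± 0.07, adjusted p = 0.00259). Foxp4 (1.76 ± 0.31, adjusted p = 0.0502), Isl1 (1.30 ± 0.55) and Hmga2 (−1.87 ± 0.61) did not pass. The cone genes Thrb (1.10 ± 0.32) and Pde6c (1.81 ± 0.48) and the rod genes Rp1 (−1.32) and Sag (−1.14) did not pass either. Whether rod and cone genes changed in progenitor-like nuclei themselves or through free photoreceptor RNA was not tested.

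**Figure D1:**
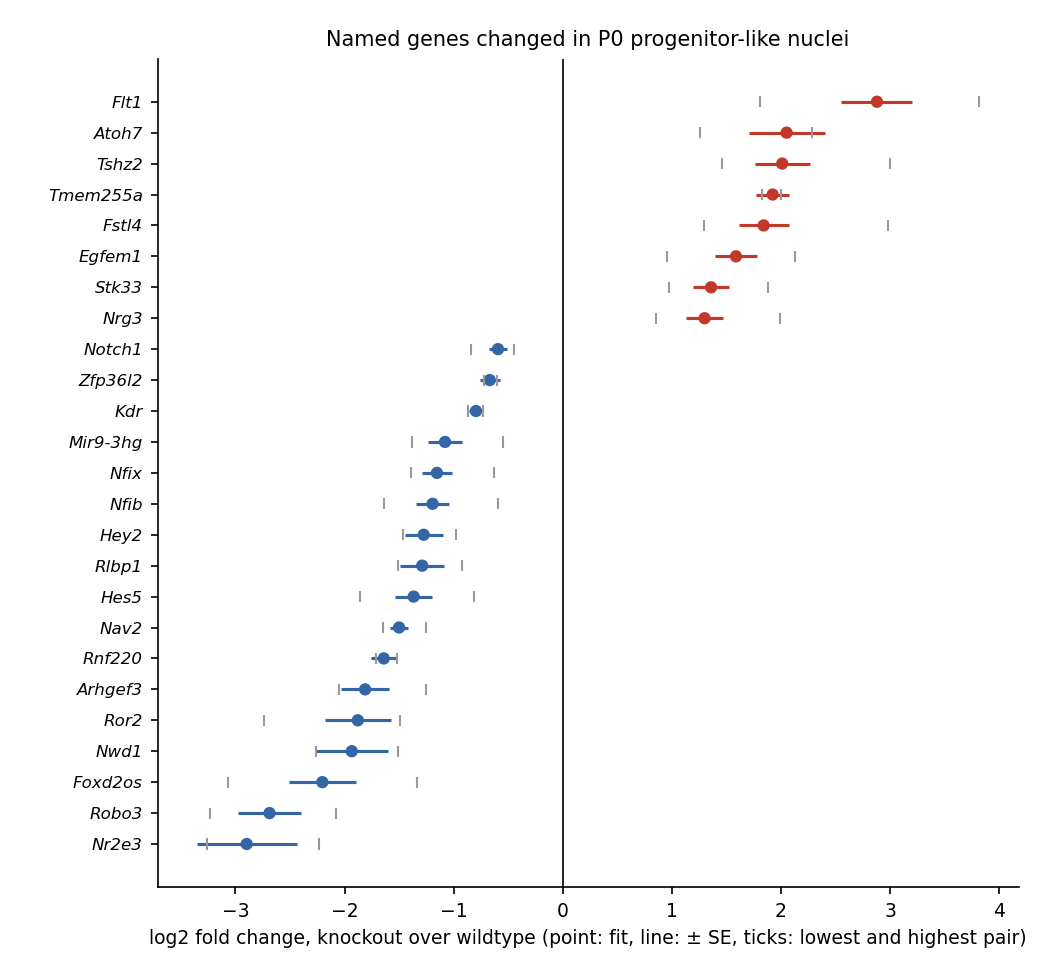
Log2 fold change (knockout over wildtype, x axis) of named genes (y axis) that passed in P0 progenitor-like nuclei, 4 and 4 libraries. Bars are ± SE and ticks the lowest and highest pair: Flt1 rose by 2.88, and Hes5 (−1.37), Nfib (−1.19) and Nfix (−1.15) fell.

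The P0 count was 0 without covariate, 373 with the December batch alone, 0 with the February batch alone, 289 by DESeq2 and 470 without the filter on low counts. Without knockout replicate 1, 2, 3 or 4 it was 48, 42, 16 or 12 genes, and without wildtype replicate 3 or 4 it was 8 or 9. Asked whether the effect of the knockout in progenitor-like nuclei differed between E16.5 and P0, the interaction called 0 of 11466 genes by edgeR (457 at an unadjusted p under 0.05, 80 called without the filter on low counts). Across 10076 genes the fold changes of the stages had r = 0.239 (rho = 0.203). A difference between stages was not shown for Hes5, Nfib or Nfix.

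At E16.5 the other classes together had 101 genes rise and 123 fall. In amacrine-like nuclei 53 rose and 47 fell of 5649. The inhibitory neuron gene Gad1 (−3.94 ± 0.57, adjusted p = 0.0047) fell with Nr4a2 (−4.57 ± 0.63, 175 to 6.26 CPM), Kcnip1 (−4.56 ± 0.38, adjusted p = 0.000412, 1016 to 41.8 CPM) and Inpp4b (−4.25 ± 0.53). Onecut1 (2.02 ± 0.28, adjusted p = 0.00365), Onecut2 (1.44 ± 0.21, adjusted p = 0.0045) and Prox1 (1.28 ± 0.20), genes of horizontal cells, rose with Arpp21 (4.21 ± 0.52, 23.0 to 374 CPM), Arhgap15 (3.74 ± 0.50) and Pmfbp1 (3.51 ± 0.53). Of 7 horizontal cell genes 3 rose (5 over the list alone; camera adjusted p = 2.57e-10, with estimated correlation p = 0.00238 and adjusted p = 0.0380). Cluster 14, led by Kcnip1 with Gad1, Inpp4b and Nr4a2, held on average over libraries 42.8 ± 25.8% of wildtype amacrine-like nuclei (19.7 to 79.9%) and 0.148 ± 0.295% in the knockout. Cluster 6, led by St18, held the others. Changes within these clusters were not tested at E16.5.

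In E16.5 retinal ganglion cell-like nuclei 35 genes rose and 58 fell of 11138. The ganglion cell factor genes Isl2 (−3.99 ± 0.29, adjusted p = 0.000222, 43.6 to 2.65 CPM) and Pou4f1 (−1.93 ± 0.17, adjusted p = 0.00075) fell with Cpne4 (−4.05 ± 0.48, 542 to 30.7 CPM) and Sh3pxd2a (−3.43 ± 0.54). Hpse2 (3.55 ± 0.32, 21.1 to 257 CPM), Lmo2 (2.01 ± 0.28), Csmd1 (1.54 ± 0.17) and Onecut1 (0.97 ± 0.10) rose. Slc17a6 fell (−0.54 ± 0.10, adjusted p = 0.036; with the pair block 0.078, not called). Cluster 7, led by Cpne4, held on average over libraries 46.8 ± 16.3% of wildtype and 0.156 ± 0.185% of knockout ganglion cell-like nuclei (lower in 4 of 4 pairs). Clusters 8 and 11 held 19.9 ± 13.0% and 10.6 ± 4.99% in wildtype and 40.3 ± 7.39% and 29.8 ± 3.20% in the knockout, higher in 4 of 4 pairs.

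In E16.5 photoreceptor-like nuclei 8 genes rose, among them Arhgef28 (2.50 ± 0.40), Muc19 (2.43 ± 0.40) and Iqgap2 (2.41 ± 0.36, adjusted p = 0.00739). There 7 fell, among them Ptpro (−2.35 ± 0.44), Rspo2 (−2.18 ± 0.44) and Epha10 (−1.79 ± 0.34). In horizontal-like nuclei (2 and 3 libraries) 5 rose, with Smoc1 (2.21 ± 0.50), Plxdc2 (2.21 ± 0.40) and Arpp21 (2.17 ± 0.42). There 11 fell, with Dab1, Adamtsl1, Prr16 and Meis2 (−2.81 ± 0.41), and the pair block called 18 and 41. In neurogenic precursor-like nuclei edgeR called 0 of 5297 genes (300 at an unadjusted p under 0.05), and DESeq2 3 higher and 2 lower. The sum of 224 over these classes was 90 without replicate pair 1, 41 without pair 3, 86 without covariate, 184 and 11 with the December and February batch alone, 430 by DESeq2 and 930 without the filter on low counts.

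At P0 the other classes had 367 genes rise and 912 fall, most in amacrine-like nuclei (205 and 505 of 10573). There Lhx9 (−5.72 ± 0.33, adjusted p = 1.34e-06, 208 to 2.54 CPM), Hmcn1 (−6.24 ± 0.33, adjusted p = 8.23e-07, 128 to 1.95 CPM) and Meis2 (−3.28 ± 0.14, adjusted p = 1.94e-07) fell, and Tfap2e went from 31.2 CPM to 0 in every knockout library. Nfib (−1.33 ± 0.30), Mef2c (−1.56 ± 0.26), Tfap2c (−0.74 ± 0.20) and Gad1 (−0.61 ± 0.11, adjusted p = 0.006) also fell. Onecut3 (3.78 ± 0.30, adjusted p = 1.61e-05, 2.09 to 30.6 CPM), Gfra3 (3.62 ± 0.35) and Pmfbp1 (2.96 ± 0.33) rose most. Onecut1 (2.15 ± 0.33), Sox2 (1.99 ± 0.17), Isl1 (1.79 ± 0.14, adjusted p = 1.35e-05), Atoh7 (1.43 ± 0.33) and the proneural gene Neurog2 (1.30 ± 0.19) also rose. Onecut2 rose (0.51 ± 0.14, adjusted p = 0.0495; with the pair block 0.0532). Cluster 13, led by Lhx9 and Hmcn1, held 30.3 to 37.2% of amacrine-like nuclei in the wildtype libraries and 0 to 0.324% in those of the knockout. Cluster 14, led by Abcc8, Isl1 and Chat, held on average 5.98 ± 2.43% and 35.8 ± 10.0%. In the December batch cluster 12 went from 34.1 and 35.7% to 72.2 and 70.9%, and cluster 6 from 25.5 and 23.7% to 0.971 and 1.18%. In the February batch cluster 6 held 55.6 and 59.9% in wildtype and 55.0 and 53.4% in the knockout.

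By list, 3 of 8 horizontal cell genes rose in P0 amacrine-like nuclei (camera adjusted p = 0.000292, with estimated correlation p = 0.00656). So did 4 of 17 neurogenic transcription factors (7 over the list alone, camera adjusted p = 0.000804, with estimated correlation p = 0.0106) and 4 of 13 early-competence genes (7 rose and 3 fell over the list alone, camera adjusted p = 0.0222, with estimated correlation p = 0.0586). Of 14 amacrine genes 3 fell (1 rose and 6 fell over the list alone, camera adjusted p = 0.0112, with estimated correlation p = 0.257). None of these 4 passed after adjustment with estimated correlation. Rod genes fell in photoreceptor-like nuclei (39 genes rose and 53 fell of 10131). Of 11 rod genes 8 fell (10 over the list alone; camera adjusted p = 2.71e-66, with estimated correlation p = 0.00106 and adjusted p = 0.0201). Cngb1 (−6.15 ± 0.53, 40.4 to 1.13 CPM), Pde6b (−5.49 ± 0.43, adjusted p = 0.000271), Sag (−4.24 ± 0.30), Nr2e3 (−3.08 ± 0.16), Rom1 (−1.97 ± 0.32) and the rod factor gene Nrl (−1.83 ± 0.30) fell with Nfib (−2.98 ± 0.21) and Mybpc1 (−4.42 ± 0.40). The cone genes Thrb (1.60 ± 0.16, adjusted p = 0.0015) and Pde6c (1.31 ± 0.18) rose with Tc2n (4.05 ± 0.52), Csmd2 (3.70 ± 0.44) and Cit (2.93 ± 0.23, 77.7 to 618 CPM). Clusters 18, led by Sag and Nr2e3, and 9, with Pde6c and Thrb among its leading genes, came mostly from the December batch. There cluster 18 held 33.7 and 32.3% of photoreceptor-like nuclei in the wildtype libraries and 0.390 and 0.497% in the knockout, and cluster 9 held 18.4 and 17.9% and 63.9 and 58.2%.

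In P0 retinal ganglion cell-like nuclei 85 genes rose and 251 fell of 10529. Myo5b (−5.71 ± 0.35, adjusted p = 2.77e-06, 73.2 to 1.32 CPM), Cpne4 (−4.51 ± 0.21, 951 to 41.5 CPM), Sorcs3 (−3.68 ± 0.40), Thy1 (−1.33 ± 0.17) and Pou4f1 (−1.08 ± 0.10) fell. Lmo2 (2.03 ± 0.26), Prkg2 (1.91 ± 0.39), Onecut1 (0.80 ± 0.12) and Hpse2 (2.76 ± 0.44, adjusted p = 0.019; with the pair block 0.108) rose. Cluster 16 held on average over libraries 21.1 ± 2.09% of wildtype and 52.6 ± 4.50% of knockout ganglion cell-like nuclei, and cluster 11 the others. Between E16.5 and P0, 59 genes were called in this class at both stages, all 59 in the same direction (2.87 expected of independent lists). In amacrine-like nuclei there were 51, of which 40 in the same direction (8.06 expected).

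In P0 horizontal-like nuclei 13 genes rose, with Sez6l (2.54 ± 0.39), Camk4 (2.29 ± 0.55) and Cngb3 (2.14 ± 0.33). There 83 fell, with the peptide gene Pyy (−4.48 ± 0.50), Shc3 (−2.83 ± 0.27), P3h2 (−2.19 ± 0.18, adjusted p = 1.48e-06, 1070 to 239 CPM), Meis2 (−1.75 ± 0.33) and the horizontal cell factor gene Lhx1 (−0.82 ± 0.16). In neurogenic precursor-like nuclei (2 and 2 libraries) 25 rose, with Tmtc1 (3.56 ± 0.57), Olfm3 (2.99 ± 0.72), Kcnab1 (2.39 ± 0.35) and Atoh7. There 20 fell, with Mybpc1 (−2.25 ± 0.24, adjusted p = 5.6e-08), Nfix (−1.74 ± 0.36) and Nfib (−1.61 ± 0.18). Nxph1 went from 26.5 CPM to 0. The pair block called 59 and 34 there. The sum of 1279 over these classes was 520 and 498 without replicate pairs 3 and 4 and 296 without covariate. It was 2018 and 426 with the December and February batch alone, and 2445 without the filter on low counts.

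The 3-week comparison asked whether the Müller glia of the knockout kept their identity after development. With all libraries as labelled (5 and 5), edgeR called 0 of 6366 genes in Müller glia-like nuclei (476 at an unadjusted p under 0.05; DESeq2 1). Ccnd1 (1.37 ± 0.35), Foxp2 (0.83 ± 0.33), Apoe (0.83), Hes1 (0.57), Tgfb2 (0.52) and Psat1 (−0.67) had folds of these sizes without passing. None of 18 tested lists was called (lowest camera adjusted p = 0.376, progenitor maintenance). Of the other classes only retinal ganglion cell-like nuclei had a call, Slc35f3 (−1.39 ± 0.22, adjusted p = 0.0152, 105 to 41.3 CPM, lower in 5 of 5 pairs), with 311 genes at an unadjusted p under 0.05. In amacrine-, bipolar-, cone-, horizontal- and rod-like nuclei edgeR called 0 (687, 575, 314, 169 and 496 at an unadjusted p under 0.05), and DESeq2 1 in bipolar-like nuclei. The 1 call over these classes was 0 without replicate pair 1, 2 or 3 and 1404 without pair 5.

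Without the libraries of replicate 5, a choice made after the data were seen, 135 genes rose and 162 fell of 7873 in 3-week Müller glia-like nuclei (4 and 4). The serotonin synthesis gene Tph2 (−5.52 ± 0.40, adjusted p = 0.000129, 92.9 to 2.49 CPM), Prkcb (−3.59 ± 0.40, 169 to 13.4 CPM), Plppr4 (−2.92 ± 0.49) and Galnt3 (−2.87 ± 0.49) fell. Brinp2 (−2.82 ± 0.41), Ahr (−2.39 ± 0.31, adjusted p = 0.00241, 81.1 to 16.2 CPM), Spc25 (−2.30 ± 0.16, adjusted p = 0.000129, 930 to 191 CPM) and Crispld1 (−2.17 ± 0.31) also fell. Mtus2 (4.72 ± 0.72, 4.25 to 76.2 CPM), Adcy2 (3.87 ± 0.61), Greb1l (3.64 ± 0.51), Nupr1 (3.56 ± 0.45), Alcam (3.53 ± 0.61), Trim30d (3.37 ± 0.48) and Aifm3 (3.11 ± 0.37) rose. The cystine transporter gene Slc7a11 (2.98 ± 0.30, adjusted p = 0.00119, 23.3 to 184 CPM), Foxp2 (1.24 ± 0.18, adjusted p = 0.00418, 324 to 797 CPM), Ccnd1 (1.56 ± 0.37), the complement gene C4b (2.25 ± 0.40) and Dapl1 (0.75 ± 0.13) rose as well. Cd44 (−0.97 ± 0.21), Thrb (−0.63 ± 0.14) and Pou2f1 (−0.77 ± 0.15) fell, and the Müller glia gene Rlbp1 did not pass (−0.85, adjusted p = 0.0617). Of 19 mature Müller glia genes 1 rose and 0 fell (median −0.07, camera adjusted p = 0.998). No list was called (lowest camera adjusted p = 0.236), and of 11 reactive gliosis genes 1 rose and 1 fell (6 and 2 over the list alone).

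Without replicate 5, 351 genes rose and 406 fell in 3-week amacrine-like nuclei, 181 and 229 in bipolar-like and 96 and 27 in rod-like nuclei. In cone-, horizontal- and retinal ganglion cell-like nuclei 20, 6 and 9 rose and 29, 24 and 26 fell. In amacrine-like nuclei Mctp1 (2.31 ± 0.12, adjusted p = 2.5e-09, 62.4 to 307 CPM), Sox2 (1.63 ± 0.23), Isl1 (1.49 ± 0.15), Hmga2 (1.41 ± 0.19) and the acetylcholine synthesis gene Chat (1.23 ± 0.15) rose. Npsr1 (−2.83 ± 0.22), Nxph2 (−2.36 ± 0.33) and Nfia (−0.70) fell. Over replicates 1 to 4 the clusters led by Chat went from 9.73 ± 3.53% to 39.5 ± 18.5% of amacrine-like nuclei, and changes within amacrine clusters were not tested at 3 weeks. Over all 5 pairs cluster 4, led by Chat and Megf11, held 13.1 ± 15.7% of amacrine-like nuclei in libraries labelled wildtype and 29.1 ± 23.6% in those labelled knockout (3 of 5 pairs), with 60.0% in knockout replicate 3. In rod-like nuclei Mctp1 (8.94 ± 0.46, 0.332 to 106 CPM), Samd4 (5.93 ± 0.42), Ptpro (4.90 ± 0.52) and the stress genes Cebpd (3.22 ± 0.40), Edn2 (2.66 ± 0.28), Stat3 (adjusted p = 0.000636) and Fgf2 (1.06 ± 0.21) rose. Dcc (−1.54 ± 0.16), Lrp2 (−1.28 ± 0.24) and C130071C03Rik (−1.72 ± 0.28, adjusted p = 0.0315) fell. Of 8 reactive gliosis genes 4 rose in rod-like nuclei (5 over the list alone; with estimated correlation p = 0.00109, adjusted p = 0.0208). Rod cluster 9, led by Edn2, held 1.52 ± 1.81% of rod-like nuclei in libraries labelled wildtype and 9.68 ± 13.0% in those labelled knockout. It was higher in the 2 pairs of the March batch only (highest 25.8%), and every library of the other batches had at most 0.747%. Fgf2 and Mctp1 were among the leading genes of this cluster as well. The rises in rod-like nuclei and the call of reactive gliosis genes there were therefore not told apart from another mix of rod clusters. Changes within rod clusters were not tested.

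In bipolar-like nuclei without replicate 5 Abcg2 (2.00 ± 0.34) and Eya4 (1.98 ± 0.25) rose. Sorcs3 (−3.13 ± 0.31), Shisa6 (−2.82 ± 0.30), Isl1 (−0.77 ± 0.13), Prkca (−0.67 ± 0.12) and Grm6 (−0.67 ± 0.13) fell. The mix of bipolar clusters shifted in the same pairs. Cluster 8, led by Grik1, rose in each of pairs 1 to 4 and held 32.5 to 38.5% of bipolar-like nuclei in their knockout libraries (12.5% in wildtype and 34.5% in knockout replicate 3). Cluster 22, with Prkca among its leading genes, fell in pairs 1 and 3 (36.2 to 21.8% in pair 1), and cluster 5, with Grm6, in pairs 2 and 4 (36.1 to 25.7% in pair 2). Changes within bipolar clusters were not tested. In cone-like nuclei Mtus2 (4.75 ± 0.56), Kcnk3 (2.37 ± 0.42) and Cntn1 (2.34 ± 0.19) rose and Trhde (−2.90 ± 0.20, adjusted p = 4.62e-09, 174 to 23.7 CPM) fell. Horizontal-like nuclei had Cntn5 rise (6.85 ± 0.55, 1.30 to 246 CPM) and Rasef (−2.36 ± 0.29), Kcnq5 (−2.31 ± 0.30) and Frmpd4 (−2.18 ± 0.23) fall. Ganglion cell-like nuclei had Tafa3 (2.69 ± 0.36) and Oprm1 (1.51 ± 0.28) rise and Prlr (−2.95 ± 0.50), Hydin (−2.36 ± 0.41) and Gpr149 (−2.29 ± 0.43) fall. In amacrine-like nuclei 179 genes were called both at P0 and at 3 weeks without replicate 5, of which 153 in the same direction (40.6 expected of independent lists). Replicate 5 was left out because it ran against the other pairs and the P0 effect, so part of this agreement follows from the choice, and with all libraries 0 genes were called in 3-week amacrine-like nuclei. With the March batch alone 163 genes were called in Müller glia-like nuclei and 828 over the other classes.

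**Figure D2:**
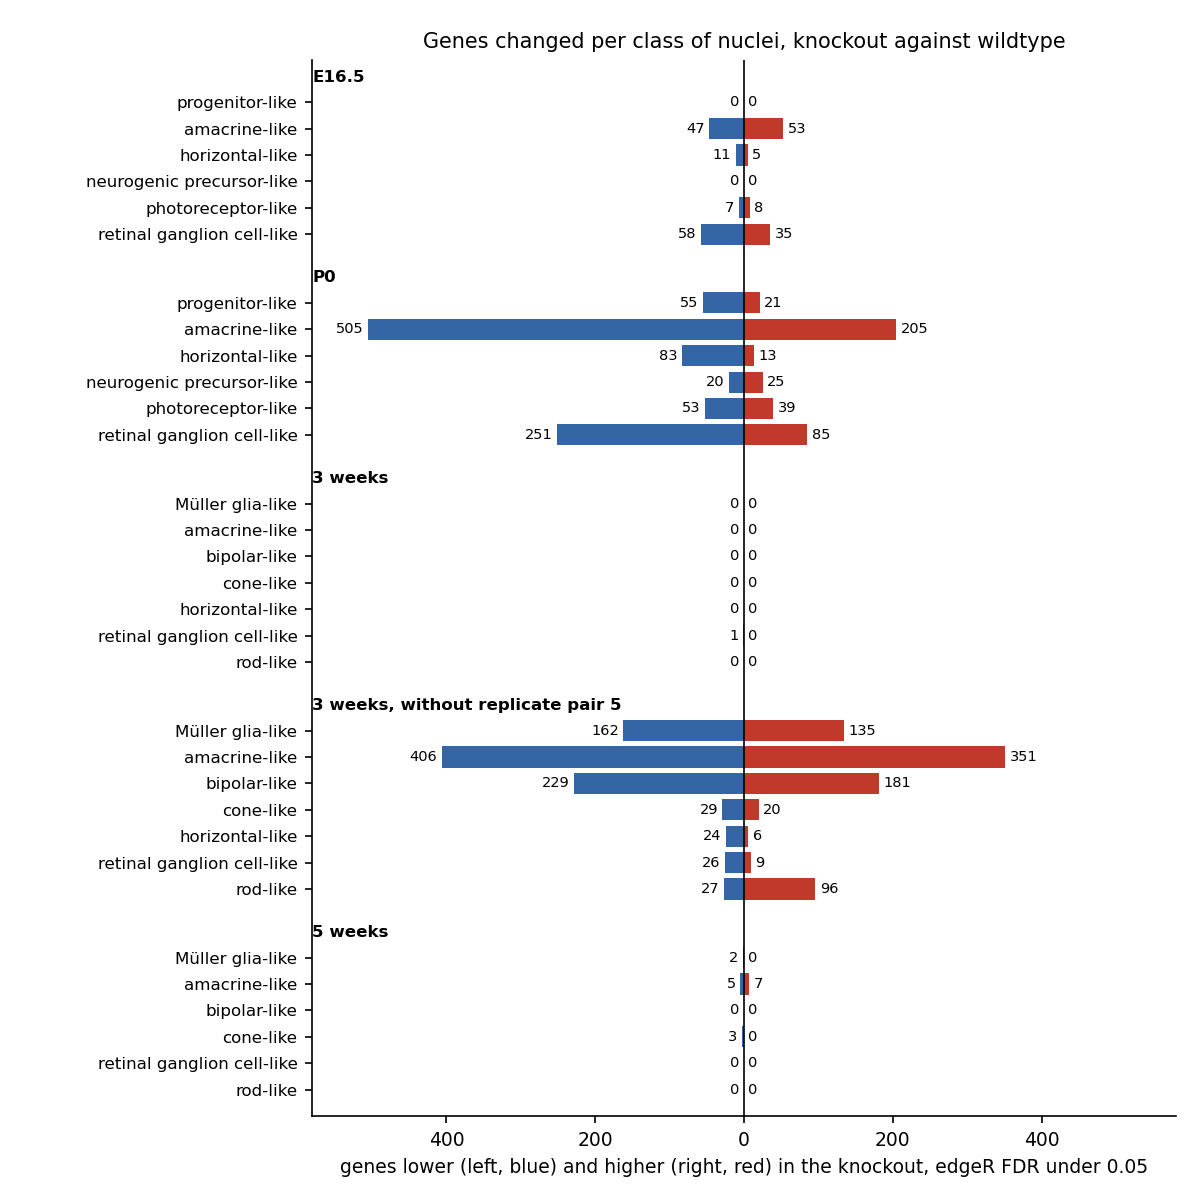
Number of genes lower (left) and higher (right) in the knockout per class of nuclei and stage (edgeR adjusted p under 0.05; x axis genes, y axis classes; 4 and 4, 4 and 4, 5 and 5 and 3 and 3 libraries), with 3 weeks also without replicate 5. Counts have no error bars: amacrine-like nuclei had the most at P0 (205 higher, 505 lower).

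The 5-week comparison asked what deleting the putative enhancer of miR-9-2 changed in the adult retina. In Müller glia-like nuclei 0 genes rose and 2 fell of 8470 (3 and 3): the host C130071C03Rik and Tenm2 (−0.82 ± 0.13, adjusted p = 0.0478, 607 to 346 CPM). The pair block called 1 and 7 there and DESeq2 0 and 4. There 112 genes were called without the filter on low counts, 27 without wildtype replicate 3, and 1 without wildtype replicate 2 or without enhancer knockout replicate 1 or 2. Foxp2 (0.68 ± 0.14, adjusted p = 0.190, 261 to 424 CPM), Agt (−0.92) and the glial factor gene Sox9 (−0.66) did not pass. Camera called 2 of 15 tested lists lower. They were the miR-9 hosts and neighbours (3 measured, 1 fell; adjusted p = 3.66e-07, with estimated correlation p = 0.00733) and late-competence genes (15, 0 fell, 1 over the list alone; adjusted p = 0.0078, estimated p = 0.126). After adjustment with estimated correlation neither passed (adjusted p = 0.110 and 0.630).

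In 5-week amacrine-like nuclei 7 genes rose and 5 fell of 11191. Hmga2 (1.78 ± 0.27, adjusted p = 0.0242, 17.9 to 62.2 CPM), Myo5b (adjusted p = 0.00809, 48.8 to 138 CPM), Igfbp7 (1.21 ± 0.18) and Sox2ot (1.27 ± 0.18, adjusted p = 0.0221; with the pair block 0.0714) rose. The glycine receptor gene Glra1 (−1.56 ± 0.24, 64.7 to 21.6 CPM), Mapk4 (−0.96 ± 0.17) and Lamp5 (−0.93 ± 0.16) fell. Cluster 21, led by Col25a1 with Chat and Sox2ot, went from 7.96 ± 2.79% to 18.4 ± 3.13% of amacrine-like nuclei (higher in 3 of 3 pairs). Cluster 27, led by Trhde, went from 14.4 ± 2.75% to 6.19 ± 2.92% (lower in 3 of 3) and cluster 33, with Lamp5, from 9.31 ± 1.32% to 6.90 ± 1.91% (higher in 1 of 3). Changes within clusters were not tested at 5 weeks. Of these 12 genes 10 were also called in 3-week amacrine-like nuclei without replicate 5, all 10 in the same direction (0.788 expected of independent lists). In cone-like nuclei Trhde (−1.09 ± 0.15, adjusted p = 0.000539, 252 to 119 CPM), Maml2 (−0.79 ± 0.14) and Pitpnc1 (−0.77 ± 0.15) fell, and Trhde and Pitpnc1 were also called lower at 3 weeks without replicate 5. Of all genes called at 3 weeks without replicate 5, 85.1% in amacrine-, 78.8% in bipolar-, 90.5% in cone-, 79.0% in rod- and 77.3% in Müller glia-like nuclei had the same sign at 5 weeks. Over all genes r was 0.269, 0.11, 0.0792, 0.119 and 0.155 in the same order, so agreement beyond the called genes was weak. In retinal ganglion cell-like nuclei only 10 of 30 called genes had the same sign, and r over all genes was −0.0795. In bipolar-, retinal ganglion cell- and rod-like nuclei edgeR called 0 (425, 305 and 191 at an unadjusted p under 0.05). DESeq2 called 3 higher and 8 lower, 1 higher, and 1 higher in the same order. The pair block called 4 higher and 6 lower in bipolar-like, 4 and 1 in ganglion cell-like and 0 in rod-like nuclei. In amacrine-like nuclei it called 36 and 41. The sum of 15 over these classes was 97 with the pair block, 71 by DESeq2 and 307 without the filter on low counts. It was 4, 9 and 70 without replicate pairs 1, 2 and 3.

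The effects of the 3-week knockout and the 5-week enhancer knockout in Müller glia-like nuclei did not differ for any of 9894 genes by edgeR as labelled (418 at an unadjusted p under 0.05; 180 called without the filter on low counts). Without replicate 5 the effect at 5 weeks was higher for 28 genes and lower for 9. Tph2 was −5.55 at 3 weeks and −1.19 at 5 weeks (difference 4.36 ± 0.52, adjusted p = 0.0014) and C130071C03Rik 0.58 and −1.12 (difference −1.70 ± 0.23, adjusted p = 0.00256). Age, kit, batch, gene annotation and allele differ together between these sets, so the differences cannot be assigned to any of them.

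Horizontal-like nuclei made up more of the knockout in every P0 pair, 0.540 ± 0.505% of kept nuclei in wildtype and 3.30 ± 3.02% in the knockout (6.11-fold, 4 of 4 pairs, exact p = 0.171, adjusted p = 0.857). Per library the share was 0.869, 1.07, 0.102 and 0.114% in wildtype and 5.65, 6.16, 0.597 and 0.787% in the knockout, and within batches it went from 0.971 to 5.90% (February) and from 0.108 to 0.692% (December). The exact test passes over the batches, and edgeR on nuclei counts with batch as covariate called the rise (log2 fold change 2.65 ± 0.16, adjusted p = 6.81e-07). Of named nuclei alone the share was 0.804 ± 0.324% and 4.77 ± 1.82% (5.93-fold, 4 of 4 pairs, exact p = 0.0286, the smallest possible, adjusted p = 0.0571). Within batches it went from 0.548 to 3.23% (December) and from 1.06 to 6.31% (February). At E16.5 the share was 1.29 ± 1.43% and 3.19 ± 3.40% (2.48-fold, 4 of 4 pairs, exact p = 0.314; 2.40 to 5.80% in the February and 0.170 to 0.572% in the December batch), and of named nuclei 2.13 ± 1.04% and 4.89 ± 2.27% (exact p = 0.0571, adjusted p = 0.171). At 3 weeks it was 1.47 ± 1.88% in libraries labelled wildtype and 3.22 ± 2.60% in those labelled knockout (2.19-fold, 4 of 5 pairs, exact p = 0.302). Replicate 5 had 4.80% in the library labelled wildtype and 0.664% in the library labelled knockout. Without it the shares were 0.642 ± 0.285% and 3.86 ± 2.51% (6.02-fold, 4 of 4 pairs, exact p = 0.0286, the smallest possible, adjusted p = 0.229; edgeR on nuclei counts adjusted p = 0.000466). Replicate 5 was the only pair with the lower share in the labelled knockout, so these p values follow in part from leaving it out. At 5 weeks it was 0.374 ± 0.130% and 0.731 ± 0.140% (1.96-fold, 3 of 3 pairs, exact p = 0.1, the smallest possible).

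Amacrine-like nuclei were a smaller part of the P0 knockout, 28.2% in wildtype and 15.0% in the knockout of the February batch and 3.84% and 2.69% of the December batch (lower in 4 of 4 pairs, exact p = 0.286; edgeR on nuclei counts −0.71 ± 0.16, adjusted p = 0.00579). Of named nuclei they fell 0.572-fold to 14.3 ± 2.75% (0 of 4 pairs higher), and P0 progenitor-like nuclei rose from 44.2 ± 0.468% to 51.6 ± 2.15% (4 of 4 pairs higher; for both, exact p = 0.0286, adjusted p = 0.0571). Bipolar-like nuclei went from 18.3% to 13.9% at 3 weeks (lower in the library labelled knockout in 5 of 5 pairs, exact p = 0.206), and cone-like nuclei from 3.51 ± 0.552% to 4.78 ± 0.391% at 5 weeks (3 of 3 pairs, exact p = 0.1). No share passed the exact test after adjustment at any stage, and edgeR on nuclei counts called the 2 at P0. Unnamed nuclei were 16.2 ± 6.47% and 12.8 ± 4.69% at 3 weeks and 6.51% and 5.68% at 5 weeks, wildtype before knockout. At E16.5 and P0 they were most of the December batch, which lowers every share of a class in that batch.

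**Figure D3:**
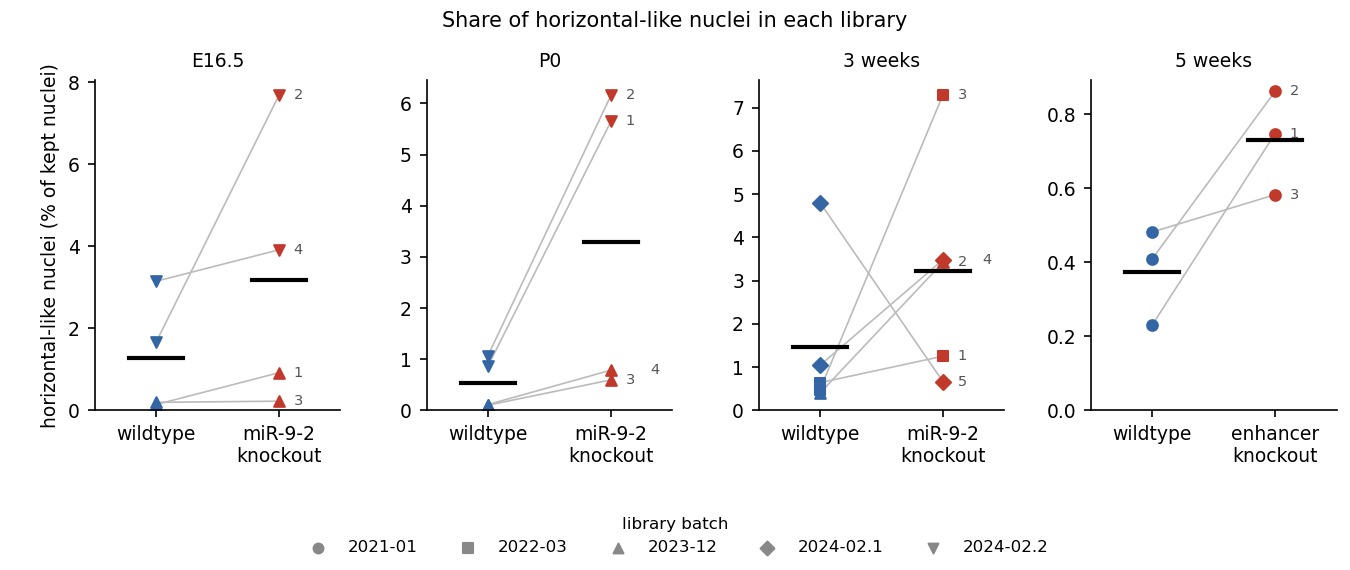
Horizontal-like nuclei (y axis, % of kept nuclei) in each library by genotype (x axis) and stage, marker shape by batch, lines joining pairs and black bars the group means (no error bars). At P0 the means were 0.540% and 3.30%, and replicate 5 at 3 weeks ran the other way (4.80% labelled wildtype, 0.664% labelled knockout).

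Genes reported as targets of miR-9 were not moved as a set in any main comparison. Of 26 measured 0 passed at E16.5, and 1 fell at P0 (Notch1; 1 rose and 1 fell over the list alone; camera adjusted p = 0.997). At 3 weeks none of 16 passed, and at 5 weeks none of 18 did (1 rose over the list alone; adjusted p = 0.0940). In amacrine-like nuclei single targets changed. At P0 Onecut1, Onecut2, Isl1, Hmga2 (1.02 ± 0.17) and Foxp4 (0.87 ± 0.21) rose and Meis2 fell, of 25 measured. Over all genes of that class 205 rose and 505 fell of 10573. The mix of its clusters changed as well. Cluster 14, with Isl1 among its leading genes, went from 5.98 ± 2.43% to 35.8 ± 10.0% of the class. The changes of these targets were therefore not told apart from another mix of amacrine types. Genes with a 3' UTR match to the miR-9-5p seed (ACCAAAG) had a median log2 fold change above that of genes without by 0.03 in E16.5 progenitor-like nuclei (rank 16 of 75 heptamers). Ranks count from the highest signed difference, among heptamers of the same base composition. The difference was −0.02 in P0 progenitor-like nuclei (rank 48), and −0.04 at 3 weeks (rank 36) and −0.01 at 5 weeks (rank 57) in Müller glia-like nuclei. In amacrine-like nuclei the seed ranked 55 at E16.5, 45 at P0, 2 at 3 weeks (7 without replicate 5) and 73 at 5 weeks. At 3 weeks its difference was −0.017, where the background heptamers had a median of −0.030 (−0.045 to −0.015). Rank 2 there thus means among the least lowered heptamers. In the progenitor- and Müller glia-like nuclei matches to miR-9-3p (AGCTTTA) ranked 277, 27, 196 and 60 of 360. All these values are of nuclear RNA, and neither mature miR-9 nor protein was measured. Mir9-3hg, the host of another miR-9 hairpin, was still read in the P0 knockout (mean 44.3 CPM over all nuclei). The target list and the seed ranks therefore leave open whether targets were released from repression.

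**Figure D4:**
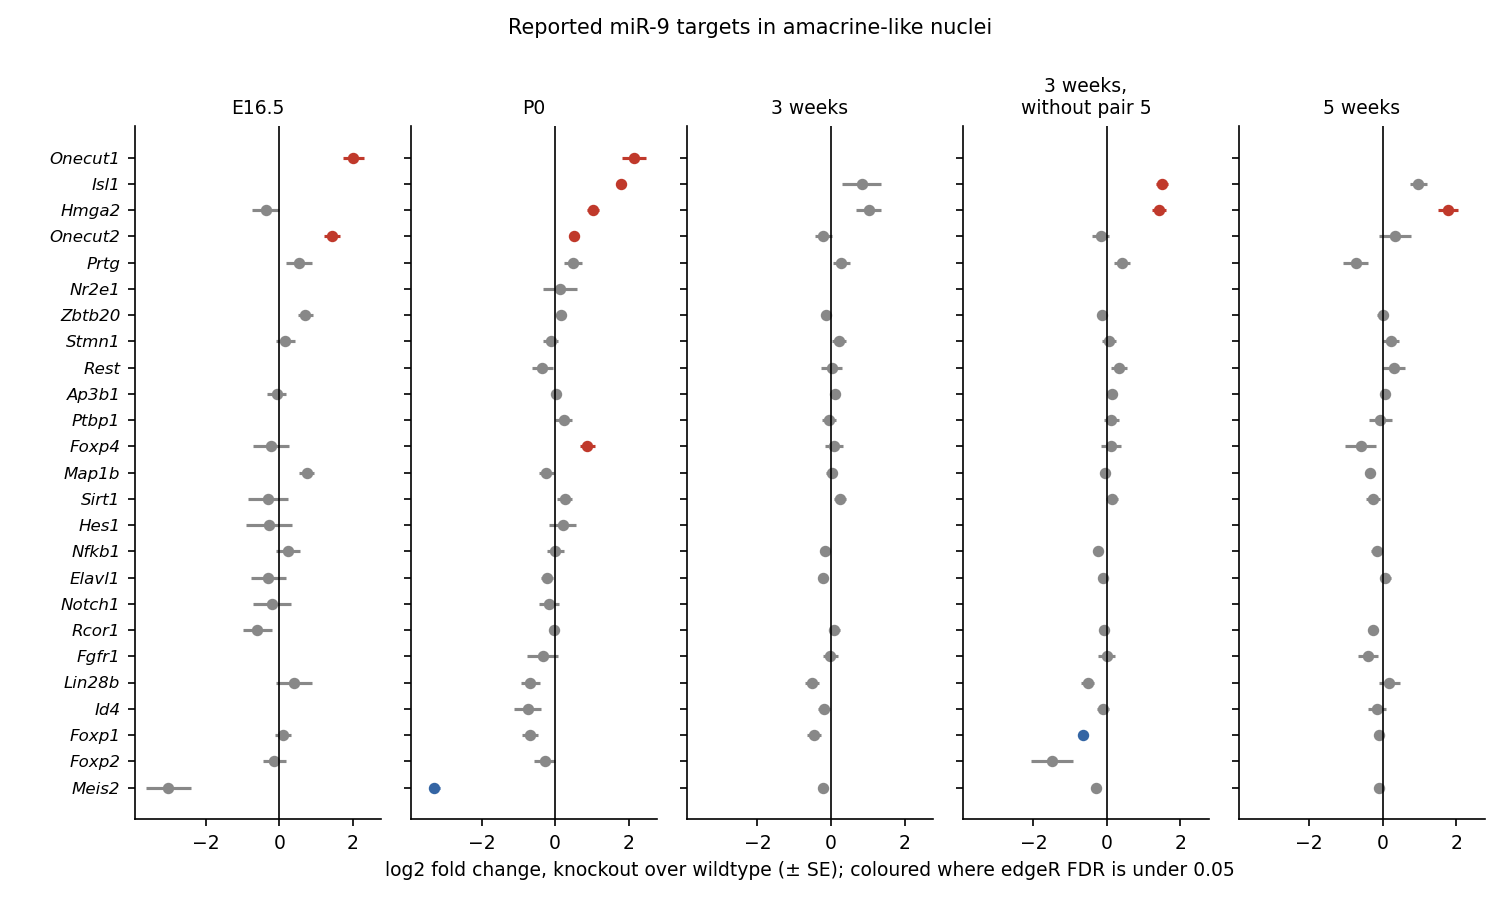
Log2 fold change (knockout over wildtype, x axis, bars ± SE) of reported miR-9 targets (y axis) in amacrine-like nuclei of each stage, with 3 weeks also without replicate 5, coloured where edgeR's adjusted p was under 0.05. Onecut1 rose by 2.02 at E16.5 and 2.15 at P0, Hmga2 by 1.78 at 5 weeks, and Meis2 fell by 3.28 at P0. The mix of amacrine clusters differed between genotypes at these stages as well.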

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

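In this part the tests on batch, on clusters made without Onecut1 and Onecut2 and on the number of nuclei per progenitor for the horizontal share, the test of free RNA between batches, the test on batch for replicate 5 and the comparison without replicate 5 were chosen after the results were seen. Of 58 groups of libraries, 4 held a value far from the others, where chance alone gives about 1 in 20 (2.9). The library labelled wildtype of replicate 5 at 3 weeks had 4.80% horizontal-like nuclei, against 1.04% in the nearest library of its group. Wildtype replicate 4 at 3 weeks had the host C130071C03Rik at 174 CPM (nearest 223) and 10753 kept nuclei (nearest 6218), and knockout replicate 3 had 10977 kept nuclei (nearest 5506). Barcodes that no class name covered, which the comparisons left out, held 13 changed genes at E16.5 (7 higher, 6 lower), 294 at P0 (110 and 184) and 2 at 5 weeks (0 and 2). At 3 weeks they held 0 by edgeR, with 516 genes at an unadjusted p under 0.05. Between the 3-week knockout without replicate 5 and the 5-week enhancer knockout the effect in Müller glia-like nuclei differed for 37 genes by the test of the difference itself, Tph2, Spc25 (−2.33 and −0.47) and Ahr (−2.41 and 0.03) among them.

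Horizontal-like nuclei were a larger part of the P0 knockout. With clusters made and named without Onecut1 and Onecut2, which rose in amacrine-like nuclei, the share was still 6.10-fold higher, against the naming by these genes as its cause, although the median of 9 other horizontal markers over all named nuclei, a test chosen before, was only 1.253-fold higher (0.861 to 2.89), between its limits. The share was higher in 4 of 4 pairs, 2 in each batch, against library batch, and the number per progenitor-like nucleus was 5.13-fold higher, against a lower share of other classes alone. A larger part of horizontal cells in the knockout retina is a candidate explanation. With named nuclei as the whole the share was 5.93-fold higher (5.89-fold in the December and 5.95-fold in the February batch), so counting unnamed nuclei in the whole did not make the rise. Open is the naming by markers itself, and with it whether horizontal nuclei stayed unnamed more often in wildtype, which was not tested.

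Genes changed in P0 amacrine-like nuclei at the same time as the clusters of that class did. Within clusters the change was 0.725 of that in the whole class (median over the called genes; 93.3% of 698 had the same sign), between the limits set beforehand, so another mix of amacrine types and a change within types cannot be told apart. Cluster 13, led by Lhx9, was almost absent from the knockout and could not be tested within. Free RNA from other cell types was tested with genes called in the amacrine-like nuclei of 1 batch and measured in the other, so that they were not chosen in the libraries compared. Of 500 genes called in the December batch 83.8% changed more, in the direction called, in amacrine-like nuclei than in unnamed barcodes of the February batch, and 91.3% of 347 the other way round (57.1% and 56.5% of genes not called). The unnamed barcodes passed the same filter as the named nuclei and can carry RNA of their own. Their change is thus no reading of free RNA alone, and free RNA as a source was not excluded. A loss of some amacrine types and a gain of others may be part of the pattern.

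The libraries of replicate 5 at 3 weeks differed over genes in the opposite direction to the other pairs (r with each other pair −0.702 to −0.0335 in 7 classes). Over genes in amacrine-like nuclei the difference labelled knockout minus labelled wildtype had r = −0.235 with the knockout effect at P0, where pairs 1 to 4 had 0.106 to 0.279, and r = −0.484 with the mean of pairs 1 to 4. Both libraries (2 of 2) lay on the other genotype's side, which argues against a single wrong label in the pair, and pair 4 of the same batch had r = 0.541 with pairs 1 to 3, which argues against library batch. Not all measures ran so: bipolar-like nuclei were 25.1% of named nuclei in the library labelled wildtype and 21.7% in the library labelled knockout, lower as in the other 4 pairs, and Slc35f3, picked out as the 1 gene that passed with all libraries, was lower in ganglion cell-like nuclei in 5 of 5 pairs. An exchange of the labels of these 2 libraries may explain the pattern over genes but leaves these measures unexplained, and the counts held no direct reading of the deletion that could decide it. The labels were kept as given, and exchanged labels were used for no reported change.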

How the results depend on the processing

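Alternatives chosen after the data were seen were each batch alone, 3 weeks without replicate pair 5 and clustering without Onecut1 and Onecut2. Under the alternatives 88 values stayed on the same side of the threshold or, for counts, within 1.5 times the count reported. Seed matches were instead judged against the range of the background heptamers. A reversal could be seen only for the host transcript and those named genes that were followed through the alternatives, where there was none. Many of these 88 were gene counts that stayed 0, in E16.5 progenitor-like and 3-week Müller glia-like nuclei and in the differences between stages. A further 11 were counts of 0 nuclei shares, which could hardly change. The smallest exact p was 0.1 with 3 and 3 and 0.0286 with 4 and 4 libraries. For the sign-flip test the smallest was 0.0625 with 5 pairs. The values below did not stay within these limits. Where the setting itself does not explain it (fewer libraries, more genes tested), the cause was not tested. No filter on low counts, which tests many more genes, gave 174 genes in E16.5 progenitor-like nuclei (0 reported), 930 in the other E16.5 classes (224), 470 in P0 progenitor-like nuclei (76), 2445 in the other P0 classes (1279), 268 in 3-week Müller glia-like nuclei (0), 427 in the other 3-week classes (1), 112 in 5-week Müller glia-like nuclei (2), 307 in the other 5-week classes (15), 80 for the interaction of E16.5 and P0 (0) and 180 for the difference of 3 and 5 weeks (0). DESeq2 called 11, 430 and 289 genes in E16.5 progenitor-like nuclei, the other E16.5 classes and P0 progenitor-like nuclei, 1 and 2 at 3 weeks (Müller glia-like, other classes) and 4 and 71 at 5 weeks. Without covariate the counts were 86 in the other E16.5 classes, 0 in P0 progenitor-like nuclei, 296 in the other P0 classes and 0 in the other 3-week classes, and with batch and sex 1 in E16.5 progenitor-like nuclei. The pair block gave 2 in the other 3-week classes, 8 in 5-week Müller glia-like nuclei and 97 in the other 5-week classes, and left the other counts within 1.5 times (251 in the other E16.5 classes, 53 in P0 progenitor-like nuclei, 1453 in the other P0 classes), but not the same genes (46 of the 76 shared in P0 progenitor-like nuclei). At least 500 genes per nucleus gave 4 in the other 3-week classes, and doublets kept 0 there and 1 in 5-week Müller glia-like nuclei. Leaving out 1 library or pair at a time gave 41 to 192 in the other E16.5 classes, 8 to 53 in P0 progenitor-like nuclei, 498 to 1643 in the other P0 classes, 0 to 297 in 3-week Müller glia-like nuclei (8 without the library labelled wildtype, 11 without the library labelled knockout and 297 without both libraries of replicate 5), 0 to 1404 in the other 3-week classes (1404 without replicate 5), 1 to 27 in 5-week Müller glia-like nuclei and 4 to 70 in the other 5-week classes. The December batch alone gave 15 in E16.5 progenitor-like nuclei, 373 in P0 progenitor-like nuclei and 2018 in the other P0 classes. The February batch alone gave 11 in the other E16.5 classes, 0 in P0 progenitor-like nuclei and 426 in the other P0 classes, and at 3 weeks the March batch alone gave 163 in Müller glia-like nuclei and 828 in the other classes, and the February batch alone 5 in the other classes. Without replicate pair 5, 37 genes differed between 3 and 5 weeks. Of nuclei shares 2 passed by edgeR on nuclei counts (0 by exact test), and of gene lists 2 with estimated correlation and 4 by fry (15 by camera). For the miR-9-5p seed at 3 weeks the difference was −0.0521 with 8mer sites (−0.0369 with 7mer sites), which moved by the background range. At 5 weeks it was −0.00255 with 8mer sites (−0.00885 with 7mer sites), which by that range counted as unmoved. Of 1201 values of named genes that passed, 879 passed also under the alternative, 322 did not and 0 reversed. These values follow 91 calls of the fits with all libraries. Genes named from the 3-week fits without replicate 5 were not followed in this way, nor were genes named in other classes only as list members. Most of the genes followed were named for having the same direction in every pair, so a reversal was hardly possible. Of simulated 2-fold changes 20.8% were recovered in E16.5 progenitor-like nuclei, 60.0% at P0, 40.7% in Müller glia-like nuclei at 3 weeks and 50.6% at 5 weeks, so a count of 0 leaves 2-fold changes open. Fewer genes could be tested where counts were fewer (4749 in E16.5 horizontal-like nuclei, with 99138 UMI in the lowest library, and 10123 in progenitor-like nuclei).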

Other observations

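In this part the comparisons of the clusters led by Chat were chosen after the data were seen, and the tests of splits and of maturation before. Starburst amacrine cells carry Chat, and the clusters of amacrine-like nuclei with Chat among their leading genes were a larger part of that class in the knockout. At P0 they were 5.98 ± 2.43% of amacrine-like nuclei in wildtype and 35.8 ± 10.0% in the knockout (5.98-fold, 4 of 4 pairs, exact p = 0.0286, the smallest possible; 3.94 to 27.1% in the December and 8.02 to 44.4% in the February batch). Clustered without the leading genes, which include Isl1, Megf11 and Sox2ot, the shares were 15.5 ± 10.1% and 59.8 ± 40.9% (3.86-fold, 4 of 4 pairs, exact p = 0.0857; 6.87 to 24.3% in the December and 24.1 to 95.2% in the February batch). These clusters took in 96.3 and 94.1% of the amacrine-like nuclei of the February knockout libraries, so there they no longer measured a part led by Chat. At 3 weeks they were 15.6 ± 13.5% in libraries labelled wildtype and 33.9 ± 20.4% in those labelled knockout (2.17-fold, 4 of 5 pairs, exact p = 0.119), with 39.1% and 11.4% in replicate 5. Knockout replicate 3 had the highest share (64.0%), and without replicate 3 the shares were 18.2 ± 14.1% and 26.4 ± 13.2% (1.45-fold, 3 of 4 pairs, exact p = 0.4). Without replicate 5 they were 9.73 ± 3.53% and 39.5 ± 18.5% (4.06-fold, 4 of 4 pairs, exact p = 0.0286; 4.13-fold clustered without the leading genes). Replicate 5 was the only pair that ran the other way and was left out after that was seen, so this p follows in part from the choice. At 5 weeks they were 7.96 ± 2.79% and 18.4 ± 3.13% in the enhancer knockout (2.31-fold, 3 of 3 pairs, exact p = 0.1, the smallest possible). No cluster at E16.5 was led by Chat.

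The sex genes Xist and Ddx3y matched the labels in 31 of 32 libraries. The exception was P0 wildtype replicate 4, labelled female, with Xist at 0.375 and Ddx3y at 68.9 CPM, where the other P0 libraries labelled female had Xist at 1852, 1910 and 2032 CPM. By the labels batch and sex are the same split at P0 (February male, December female). By these counts P0 pair 4 was not sex-matched, and the December wildtype held both sexes. Without this library 9 genes were called in P0 progenitor-like nuclei, against 8 without wildtype replicate 3, whose sex genes matched. How far sex moved the P0 calls, also with the December batch alone, was not tested.

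Whether other splits of the libraries gave as many genes was counted for each comparison. At P0 the real split gave 76 genes in progenitor-like nuclei and 1279 in the other classes, and at E16.5 224 in the other classes; in each case 2 of 35 splits gave as many, the real split and the split that follows the batches (7122, 14469 and 4779 genes), so over all 35 splits chance cannot be excluded. The batch split cannot hold the batch term, so its count comes from a fit without that term and cannot be compared with the others. Only 8 of the 35 splits part all pairs, the real split among them, which is too few to exclude chance by those alone. Every other split has both genotypes on both sides, so a real difference between genotypes widens the spread within its groups and can lower its count. Among the 34 splits fitted with the batch term the highest other gave 0, 45 and 28 genes, and among those that part all pairs 0, 45 and 16. The 45 equals the real calls in P0 neurogenic precursor-like nuclei (25 higher, 20 lower), and the 16 those in E16.5 horizontal-like nuclei (5 and 11). Only some libraries were tested in these classes, and a split that leaves those in their real groups repeats the real calls. The batch split points to a structure of the samples, the reason for the batch term. At E16.5 the real split gave 0 genes in progenitor-like nuclei, which every split reaches (35 of 35; highest other 4033, the batch split, and 6 with the batch term), so this count says nothing about chance. The same holds for the 0 genes in Müller glia-like nuclei at 3 weeks (100 of 100 drawn splits, highest other 393). In the other 3-week classes 7 of 25 splits gave as many as the 1 gene (highest other 151), and chance cannot be excluded. The split with 393 genes parts all pairs and differs from the real split in the 2 libraries of replicate 5, a structure of the samples. At 5 weeks the 10 splits of 6 libraries are too few for this test (2 genes in Müller glia-like nuclei, highest other 3, reached by 3 splits; 15 in the other classes, highest other 15, reached by 2).

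Nfib and Nfix, which rise as progenitors age, fell at P0, so a delayed maturation of progenitor-like nuclei was tested as a hypothesis. The knockout effect at P0 had r = −0.116 over genes with the change from E16.5 to P0 in wildtype (−0.0269 and −0.204 by the batches used), between the limits set beforehand. A delay may be part of the change, and this value leaves it open.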
